A study of Mus musculus with 24 samples.

How the data were processed

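RNA of isolated mouse retinal pigment epithelium (RPE) cells was measured in 24 libraries, 4 for each of 2 genotypes at 3 ages, made with a kit that primes at the poly(A) tail and yields 1 tag per transcript near its 3' end. Whole-number counts per gene were deposited, 1 file per library; STAR and the mm10 build are named in the submitters' processing notes, without versions. The counting tool, the annotation, the use of strand and any use of molecular identifiers are not given in the sources used here. Each deposited file held 31053 gene identifiers with their counts and 5 special entries that name no gene. The special entries stayed out of library sizes and tests. Reads assigned to no feature made up 18.6% to 27.5% of all entries of a library, ambiguous reads 0.192% to 0.322%, reads aligned to several places 31% to 37.2%, and the other 2 special entries were at 0. Gene symbols and positions came from a GENCODE annotation of GRCm38, the same assembly as mm10, in which 31011 identifiers were found and 42 were not, and 30934 matched a symbol while 119 did not.

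Samples were grouped by the genotype and age in the labels, and groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter on groups and a robust fit, on all 24 libraries with 1 mean per group. The fit kept the default prior count of edgeR, and a prior count of 1 entered only the log2 CPM values of markers, scores and library comparisons. The filter left 12303 genes, called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were mutant against control at each age, P29 against P11 and 3M against P29 in controls, and the difference of the genotype effect between ages. Standard errors are the log2 fold change divided by the root of the F value. CPM values are scaled by TMM factors, which ran from 0.937 to 1.049. Precision is limited by depth: the floor of 3 counts lay between 1.04 and 1.98 CPM, and intervals and floors cover counting error only. A fold against a group with no count is a bound over the group floor of 3 counts. For a group with 1 to 3 counts the ratio of depth-scaled group counts is given with a 95% exact binomial interval, a step added after the values were seen.

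Gene lists numbered 28 for pathways and 16 for cell types, of which 41 had at least 5 tested genes. They were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. An estimated correlation and fry were alternatives. The lists for lymphocytes (0 tested genes), mast cells (2) and ciliary body and iris (3) were too small for this test. Markers were also compared by an exact two-sided permutation test of the mean log2 CPM over 70 assignments, for the 15 cell type lists with a tested gene. The named genes were to be Ift20, the 10 largest rises and falls of each comparison among called genes with a mean of at least 5 CPM in 1 group and no overlap between groups, up to 3 members of each list with the smallest p, and the 10 genes with the smallest interaction p. Some genes that this rule takes are not reported here. Unnamed gene models were left out. The text names only the first 5 rises and falls and the first 1 or 2 members of the lists it describes, a restriction made after values and the calls lost on leaving out libraries had been seen.

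Alternatives were median-of-ratios size factors, DESeq2 1.42.0, voom with quality weights, no low-count filter (19634 genes), a stricter filter of 5 CPM in 4 libraries (11931 genes), a fit to only the 8 libraries compared, the replicate number as a block, a rod marker score or a sex score as a covariate, and leaving out each library in turn. A test against a 1.5-fold change and calls on autosomal genes alone were added after the data were seen. Replicates were compared by a chi-square test of their counts: all 36 pairs within groups differed by more than sampling noise (chi-square per gene 2.98 to 7.15), so no pair was taken as 1 library deposited again. Library preparation alone can give such values, so they do not show that the libraries came from separate animals.

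The test was checked on simulated counts with 200 changed genes among 12303. The changed genes were drawn from those with a mean over 5 CPM, so the shares do not hold for genes of lower level. Of genes changed 1.5, 2 and 4-fold, edgeR recovered 28.4%, 55.2% and 89.4% for mutant against control at P11, with 10 false calls. It recovered 17.9%, 52.2% and 97% at P29, with 3 false calls, and 19.4%, 58.2% and 90.9% at 3M, with 3. In controls it recovered 19.4%, 55.2% and 95.5% for P29 against P11, with 6 false calls, and 22.4%, 58.2% and 95.5% for 3M against P29, with 6. For the interaction the shares were 8.96%, 26.9% and 77.3%, with 7 false calls. Simulations with no effect gave 0 called genes and 0 lists at each of the 3 ages, and a lysosome list doubled at P11 was recovered with 0 other lists. Each gene was drawn independently, so these runs do not check the list test where members of a list vary together.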

Results

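The retinal pigment epithelium (RPE) is the pigmented cell layer behind the retina that recycles the light-sensitive chromophore and takes up shed photoreceptor outer segments. RNA of isolated mouse RPE cells was counted in 24 libraries made with a kit that reads the 3' ends of polyadenylated transcripts. Control animals carried the Dct-Cre driver, which acts in pigment cells, and mutant animals carried the driver with the floxed Ift20 gene. Each genotype was collected at postnatal day 11 (P11), postnatal day 29 (P29) and 3 months (3M), with 4 libraries in each of the 6 groups. Total gene counts ran from 1513440 to 2889946 per library, with a median of 2387000, and 13132 to 14709 genes had a count. The floor of 3 counts lay between 1.04 and 1.98 CPM, the counts scaled to a common library total, and covers counting error only. The biological coefficient of variation within a group ran from 12.9% in 3M mutants to 23.4% in P11 controls. The labels number the 4 libraries of a group as biological replicates without saying whether each came from 1 animal or a pool, and the extraction label has RNA being mixed without naming what was combined, so p-values measure only the spread between these libraries, which may be technical. Sex was not recorded, and the strain background was mixed. Whether the counting used strand is not stated, so genes whose 3' end overlaps another gene are uncertain: among those named Car14, Pmel, B2m, Opn1sw, Ogn, Plvap, Gfap, Mip, Cep290, Cryaa, Cryba1, Crtap, Nefl, Kcnj13, Serpine3, Timp3, Col4a3, Manf, Thoc6, Slc16a8, Ciart, Mmp24, Krt6a and Xist overlap a gene on the other strand, Egfl7 one on each, and Ctsd, Mobp, Trf and Ifi203 one on the same strand.

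Ift20 encodes a subunit of the intraflagellar transport machinery that builds cilia, and it is the gene targeted in the mutants. Its mean level was 103 CPM ± 36.8 (SD, n = 4) in controls and 85.6 CPM ± 8.22 in mutants at P11, 108 CPM ± 18.3 and 71.3 CPM ± 12.8 at P29, and 134 CPM ± 18.3 and 111 CPM ± 9.4 at 3M. The log2 fold change was -0.27 (SE 0.16, edgeR adjusted p = 0.353) at P11, -0.60 (SE 0.15, adjusted p = 0.0112) at P29 and -0.26 (SE 0.15, adjusted p = 0.547) at 3M. In the mouse annotation of the GRCm38 build the gene (ENSMUSG00000001105) lies on the plus strand of chromosome 11 from 78536361 to 78541737, and its annotated transcripts differ in their last exon, which spans 78541361 to 78541737 in the longest and starts at 78540895 in others. Which exons were floxed is not given in the sources used here, and a 3' tag can lie outside a deleted exon, so these values do not check the genotype labels. Leaving out 1 library moved the P11 value to between -0.45 (without control replicate 3, edgeR adjusted p = 0.0642) and -0.04 (without control replicate 4, adjusted p = 0.931), and the 3M value to -0.17 without control replicate 2 (adjusted p = 0.826). The P29 call was lost without control replicate 1 (log2 fold change -0.54, edgeR adjusted p = 0.0711), control replicate 3 (-0.53, adjusted p = 0.0750) or mutant replicate 2 (-0.51, adjusted p = 0.0962), and with a rod marker score (-1.13, adjusted p = 0.908) or a sex score (-0.70, adjusted p = 0.472) of each library as a covariate.

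**Figure D1:**
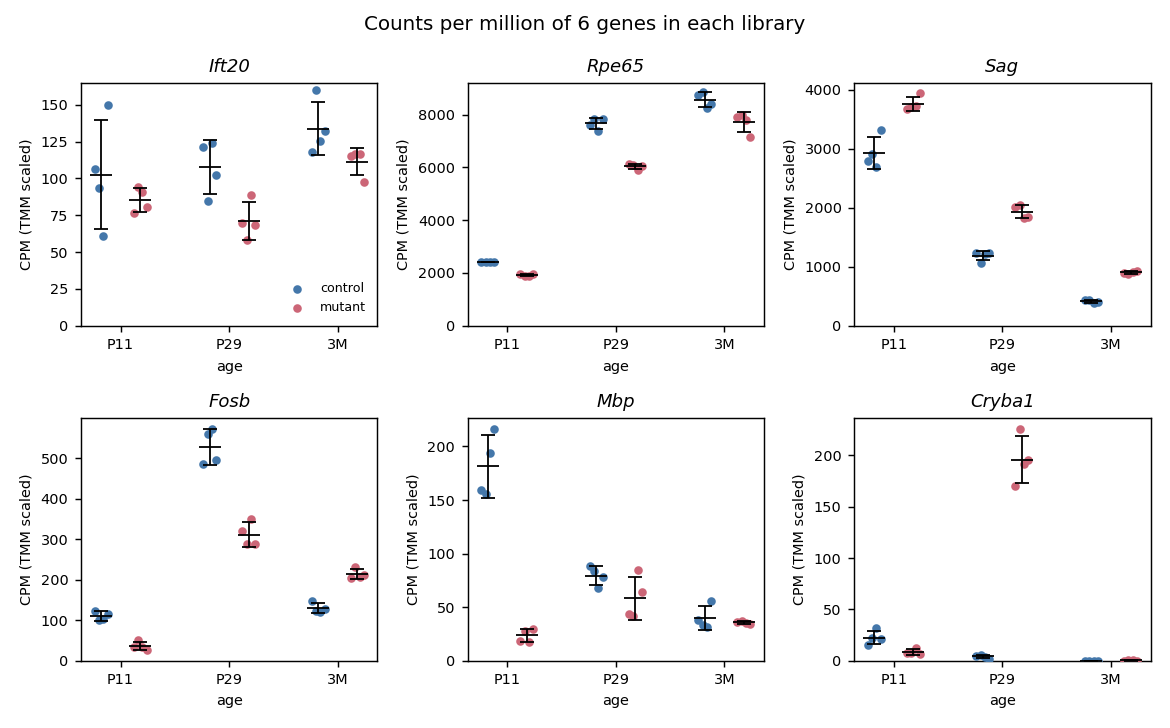
Level of 6 genes in each library, in CPM scaled by TMM factors (y axis, from 0) against age (x axis), with controls in blue and mutants in red; each point is 1 library, and the horizontal mark and bar give the mean and SD of 4. Sag was higher in mutants at every age (1930 against 1180 CPM at P29), Mbp was lower in P11 mutants (23.5 against 181 CPM) and Cryba1 was higher in P29 mutants (196 against 4.07 CPM).

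At P11 the comparison asked which transcripts of isolated RPE differ when Ift20 is targeted in the second postnatal week. Genes of the visual cycle, basement membrane and immediate early lists were among those lower in mutants. In GRCm38 Rpe65 (ENSMUSG00000028174) lies on chromosome 3 from 159599175 to 159625321, Fosb (ENSMUSG00000003545) on chromosome 7 from 19302696 to 19310051 and Mbp (ENSMUSG00000041607) on chromosome 18 from 82475146 to 82585637. Of 12 visual cycle genes, which regenerate the light-sensitive chromophore, 7 fell (9 adjusted over the list alone). The isomerase Rpe65 went from 2410 CPM ± 12.7 in controls to 1930 CPM ± 37.5 in mutants (SD, n = 4). Basement membrane genes fell in 11 of 21 (14 over the list alone), with log2 fold changes of -1.13 (SE 0.19) for the elastin gene Eln and -0.28 (SE 0.04) for Timp3, an inhibitor of matrix metalloproteinases. Immediate early genes, which respond within minutes to a stimulus, fell in 12 of 14 members (13 over the list alone), among them Fosb at -1.61 (SE 0.13, edgeR adjusted p = 9.5e-19) and Nr4a1 at -2.06 (SE 0.22). In all, 401 genes were higher and 452 lower in mutants among the 12303 tested, and voom with quality weights gave 325 and 298. Beside these changes mitochondrial transcripts took 10.8% of counts in P11 mutants against 7.81% in controls, and the share of reads assigned to no feature was 3.62 percentage points above the 23.4% of controls (exact permutation p = 0.0286 and adjusted p = 0.114 for each, over all technical measures, n = 4).

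Further gene lists fell at P11, while the list of epithelial junctions and keratins, with 2 of 20 members lower (1 higher and 2 lower over the list alone), did not pass as a set (limma camera adjusted p = 0.179). Pigment genes fell in 5 of 14 (6 over the list alone), with Pmel, a fibril protein of the melanosome, at -0.49 (SE 0.08) and the melanin enzyme Tyrp1 at -0.48 (SE 0.09). Ion and metabolite transport genes fell in 7 of 18 (8 over the list alone), with the lactate transporter Slc16a1 at -0.46 (SE 0.06) and the carbonic anhydrase Car14 at -0.35 (SE 0.06). Lysosome genes fell in 5 of 22 (10 over the list alone), with Npc2 at -0.46 (SE 0.08) and the protease Ctsd at -0.30 (SE 0.05). Phagocytosis genes fell in 4 of 17 (5), Wnt pathway genes in 3 of 15 (6), TGF-beta and BMP targets in 4 of 18 (6) and antigen presentation genes in 4 of 13 (6). In these lists Nog, an antagonist of BMP, had -2.15 (SE 0.27), Id3 -0.72 (SE 0.13), B2m -0.46 (SE 0.08) and H2-Eb1 -1.75 (SE 0.43). Of the 28 genes of intraflagellar transport 1 rose, the kinesin subunit Kif3a, at 0.66 (SE 0.19, edgeR adjusted p = 0.0185). None of 13 BBSome genes or 10 Hedgehog pathway genes passed at any age, while over the list alone 2 BBSome genes were higher at P29 and 1 at 3M. Transition zone and basal body genes rose in 4 of 23 (6 over the list alone), with Ahi1 at 0.54 (SE 0.11) and Cep290 at 0.46 (SE 0.11), and the call of the list was lost with an estimated correlation (limma camera adjusted p = 0.163).

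Markers of other cell types also separated the P11 groups. Myelin genes fell in 5 of 6 (6 over the list alone), with Mbp at 23.5 CPM ± 6.12 in mutants against 181 CPM ± 29.2 in controls (SD, n = 4). Endothelial genes fell in 7 of 13 (9), with Plvap at -2.25 (SE 0.35) and Egfl7 at -1.91 (SE 0.35). Pericyte genes fell in 3 of 6 (5), with Rgs5 at -0.98 (SE 0.13) and Cspg4 at -1.0 (SE 0.24). Stromal fibroblast genes fell in 2 of 11 (2), which were Dcn at -0.47 (SE 0.08) and Ogn at -0.72 (SE 0.20). Lens genes fell in 5 of 14 (9), with Cryba1 at -1.40 (SE 0.28) and Mip at -1.64 (SE 0.37). Rod genes rose in 7 of 16 (8), with Rom1 at 0.68 (SE 0.08) and Sag at 0.36 (SE 0.06). Inner retinal neuron genes rose in 2 of 14 (4), which were Tfap2b at 1.02 (SE 0.21) and Prkca at 0.59 (SE 0.16). Of the 8 cone genes Opn1sw rose at 0.67 (SE 0.19), and of the 7 glial genes Gfap fell at -2.97 (SE 0.44), with 2 higher and 1 lower over the list alone. The glial list had a median of 0.28 and did not pass as a set (limma camera adjusted p = 0.302). As list means on the log2 scale, mutants minus controls were -1.5 for endothelium, -1.23 for pericytes, -0.48 for stromal fibroblasts and -3.42 for myelin. A differing share of such cells was not excluded for the basement membrane, Wnt, TGF-beta and BMP, and antigen presentation genes that fell. The P11 comparison therefore does not place those falls in the RPE.

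The 5 largest rises at P11 among genes with separated groups were Krt6a, Lhx3, Asprv1, Chp2 and Vax2, and the 5 largest falls were Avp, Mobp, Bcas1, Mag and Exoc3l2. Krt6a, a keratin of stratified epithelium, had no count in controls and 54 in mutants, at least 16.5-fold higher over the group floor of 3 counts. Avp, the vasopressin precursor, had 325 counts in controls and none in mutants, at least 109-fold lower. Lhx3 rose by 3.90 on the log2 scale (SE 1.01), Asprv1 by 2.93 (SE 0.98), Chp2 by 2.88 (SE 0.60) and Vax2, a homeobox gene of the ventral eye, by 2.33 (SE 0.56). Bcas1 and Mag, both of myelinating glia, had log2 fold changes of -4.83 (SE 1.07) and -3.75 (SE 0.70), and Exoc3l2 -3.63 (SE 1.04). Mobp, also of myelin, had 315 counts in controls and 1 in mutants, a ratio of 351 with a 95% exact counting interval of 62.5 to 13900.

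Of the 41 lists tested with camera, 24 passed at P11, 4 upwards and 20 downwards, and 18 passed with an estimated correlation. The visual cycle (camera adjusted p = 2.29e-08, and 0.00261 with an estimated correlation), basement membrane (1.45e-16 and 2.52e-06), immediate early (1.19e-13 and 1.16e-05), myelin (2.01e-15 and 6.09e-06) and rod lists (1.76e-09 and 1.82e-05) were among those that held. Calls lost with the estimated correlation were transition zone and basal body (adjusted p = 0.163), epithelial-mesenchymal transition (0.0589), antioxidant genes (0.0707), choroidal melanocyte (0.0728), microglia (0.0634) and erythrocyte (0.240), whose median was 0.05 and mean -0.06 for a test directed upwards. The cell cycle list passed downwards (limma camera adjusted p = 0.0216) with none of its 15 members past the threshold singly, and it was lost without control replicate 4 (0.0764), mutant replicate 1 (0.0854) or mutant replicate 4 (0.0524). With the rod marker score of each library as a covariate 24 genes were higher and 63 lower in edgeR, with 99.8% of the variance of that score lying between groups.

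Some P11 calls no longer passed with 1 library left out. Asprv1 passed without control replicate 3 and lost its call without each of the other 7 libraries, with adjusted p from 0.0519 (without control replicate 2) to 0.168 (without control replicate 1) and log2 fold changes of 2.42 to 3.40. Exoc3l2 was lost without control replicate 2 (edgeR adjusted p = 0.0692), mutant replicate 3 (0.0837) or mutant replicate 4 (0.0878). Kif3a was lost without control replicate 3 (0.0803) or mutant replicate 3 (0.0682). Prkca was lost without control replicate 3 (0.0643) or mutant replicate 4 (0.115). Ogn was lost without control replicate 3 (0.154) or mutant replicate 2 (0.0698). Opn1sw was lost without control replicate 1 (0.0816), mutant replicate 1 (0.0600) or mutant replicate 4 (0.115). The transition zone list was lost without control replicate 3 (0.170), mutant replicate 2 (0.0616) or mutant replicate 4 (0.0911). The antioxidant list was lost without control replicate 3 (0.0863), control replicate 4 (0.0917), mutant replicate 1 (0.0505) or mutant replicate 2 (0.0612). The melanocyte list was lost without control replicate 2 (0.0871), control replicate 4 (0.0690), mutant replicate 2 (0.0567) or mutant replicate 3 (0.0667). The microglia list was lost without control replicate 2 (0.0871), control replicate 4 (0.0862), mutant replicate 1 (0.0608) or mutant replicate 4 (0.0898). The erythrocyte list was lost without control replicate 1 (0.162), control replicate 4 (0.174) or mutant replicate 4 (0.233).

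At P29 the comparison asked the same question at a later age. Lens and rod transcripts were higher in mutants, and visual cycle and immediate early transcripts were lower. Of 14 lens genes 13 rose (13 adjusted over the list alone), led by the crystallins Cryba1, at 196 CPM ± 22.7 in mutants against 4.07 CPM ± 1.77 in controls (SD, n = 4), and Crygs, at 97.2 CPM ± 12.7 against 3.47 CPM ± 2.15. Of 16 rod genes 15 rose (16 over the list alone), with the arrestin Sag at 0.70 (SE 0.06, edgeR adjusted p = 1.64e-17) on the log2 scale. Visual cycle genes fell in 6 of 12 (8), with Rgr at 3970 CPM ± 122 in mutants against 5520 CPM ± 141 in controls and Rpe65 at 6040 CPM ± 98.2 against 7670 CPM ± 219. Cryba1 (ENSMUSG00000000724) lies on chromosome 11 from 77718615 to 77725283 and Sag (ENSMUSG00000056055) on chromosome 1 from 87803680 to 87845158. In all, 201 genes were higher and 149 lower in mutants, against 195 and 223 with voom. In the same libraries reads aligned to several places were 32.4% of all entries in mutants and 31.3% in controls (exact permutation p = 0.0286, adjusted p = 0.114, n = 4).

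Immediate early genes fell in 6 of 14 at P29 (1 higher and 7 lower over the list alone), with the transcription factors Egr1 at -0.66 (SE 0.08) and Fosb at -0.76 (SE 0.10). Ion and metabolite transport genes fell in 4 of 18 (1 higher and 6 lower over the list alone), with the potassium channel Kcnj13 at -0.42 (SE 0.08) and the bicarbonate transporter Slc4a5 at -0.31 (SE 0.06). Lysosome genes fell in 2 of 22 (4), which were Ctsd at -0.22 (SE 0.05) and Psap at -0.24 (SE 0.06). Pigment genes went the other way: 3 of 14 rose (3), with Mlana at 0.67 (SE 0.15) and Pmel at 0.32 (SE 0.08), while the list as a set did not pass (limma camera adjusted p = 0.0767). Glycolysis genes rose in 2 of 16 (2), the hexokinases Hk2 at 0.85 (SE 0.16) and Hk1 at 0.40 (SE 0.10). Cholesterol synthesis and lipid genes fell in 2 of 18 (3), Hmgcs1 at -0.53 (SE 0.12) and Apoe at -0.20 (SE 0.05). Endothelial genes rose in 1 of 13 (3), Esam at 2.19 (SE 0.52). Inner retinal neuron genes rose in 2 of 14 (2), Nefl at 1.38 (SE 0.33) and Grm6, with 11 counts in mutants and none in controls, at least 3.84-fold higher over a group floor of 3 counts. Erythrocyte genes rose in 4 of 6 (4 higher and 1 lower over the list alone), with Hbb-bs at 0.38 (SE 0.05) and Hba-a2 at 0.44 (SE 0.06), and the list was lost with an estimated correlation (limma camera adjusted p = 0.0735). The circadian list fell with 1 of 14 members past the threshold (1), Per1 at -0.91 (SE 0.24). The antigen presentation list fell with 1 of 13 (4), B2m at -0.28 (SE 0.07). The epithelial-mesenchymal list rose with 1 of 24 (1), Thbs1 at 0.61 (SE 0.09), and was lost with an estimated correlation (limma camera adjusted p = 0.155).

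The 5 largest rises at P29 were Crygf, Bfsp1, Crygb, Cryba2 and Krt5, of which the first 4 encode lens proteins and Krt5 a keratin of basal epithelium. Crygf had no count in controls and 95 in mutants, at least 33.3-fold higher over the group floor of 3 counts. Crygb reached 231 CPM ± 24.0 in mutants against 3.97 CPM ± 3.97 in controls (SD, n = 4), and Cryba2 56.6 CPM ± 4.53 against 1.03 CPM ± 0.928. Bfsp1 had 213 counts in mutants and 1 in controls (ratio 223, 95% exact counting interval 39.5 to 8840), and Krt5 164 and 3 (ratio 57.2, interval 19.2 to 280). The gamma crystallins are near-identical paralogs, and how the counting assigned reads they share is not stated, which holds for Hba-a2 and Hbb-bs among the globins too. The 5 largest falls were Kdm5d, Ddx3y, Iigp1, Crtap and Serpine3, with log2 fold changes of -2.32 (SE 0.38), -1.95 (SE 0.14), -1.81 (SE 0.50), -1.70 (SE 0.51) and -1.65 (SE 0.23). Kdm5d and Ddx3y lie on the Y chromosome. Ddx3y was at 41.6 CPM ± 3.70 in mutants against 161 CPM ± 14.1 in controls, and Xist, the RNA of the inactive X chromosome, was at 465 CPM in mutants against 149 CPM in controls.

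At P29 14 of 41 lists passed in camera, 6 upwards and 8 downwards, and 12 passed with an estimated correlation. The lens (camera adjusted p = 3.27e-52, and 5.59e-11 with an estimated correlation), rod (8.92e-58 and 3.83e-11) and visual cycle lists (3.24e-24 and 1.27e-05) held, and the interferon list passed downwards (0.00788 and 0.0154) with none of its 19 members past the threshold singly. Lost with the estimated correlation were the epithelial-mesenchymal (adjusted p = 0.155) and erythrocyte (0.0735) lists, the latter with a median of 0.35 and a mean of -0.26. The transport list, which passed downwards, had a median of -0.11 and a mean of 0.02. With the rod score as a covariate 2 genes were higher and 1 lower, and with a sex score (Xist minus 4 Y-linked genes) 31 were higher and 24 lower, with 97.1% of the variance of the sex score lying between groups.

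Several P29 calls no longer passed with 1 library left out. Iigp1 passed without control replicate 3 and was lost without each of the other 7 libraries (adjusted p from 0.0553 without mutant replicate 3 to 0.0811 without control replicate 1, log2 fold changes from -1.87 to -1.75). Crtap passed without control replicate 3 or mutant replicate 1 and was lost without each of the other 6 (0.0861 without control replicate 1 to 0.180 without mutant replicate 3). Grm6 passed without mutant replicates 2 or 3 and was lost without each of the other 6 (0.0766 without control replicate 4 to 0.290 without mutant replicate 4). Psap was lost without control replicate 1 (0.0696), control replicate 4 (0.0853) or mutant replicate 4 (0.0857). Pmel was lost without control replicate 3 (0.0616), mutant replicate 1 (0.0603) or mutant replicate 4 (0.0521). Nefl was lost without control replicate 4 (0.0534). B2m was lost without control replicate 2 (0.0548), control replicate 3 (0.104), mutant replicate 2 (0.0504) or mutant replicate 4 (0.0572). Per1 was lost without control replicate 1 (0.108), control replicate 2 (0.105), mutant replicate 3 (0.0727) or mutant replicate 4 (0.0762). Hk1 was lost without mutant replicate 4 (0.0595). The epithelial-mesenchymal list was lost without control replicate 4 (0.0703) or mutant replicate 3 (0.0516).

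**Figure D2:**
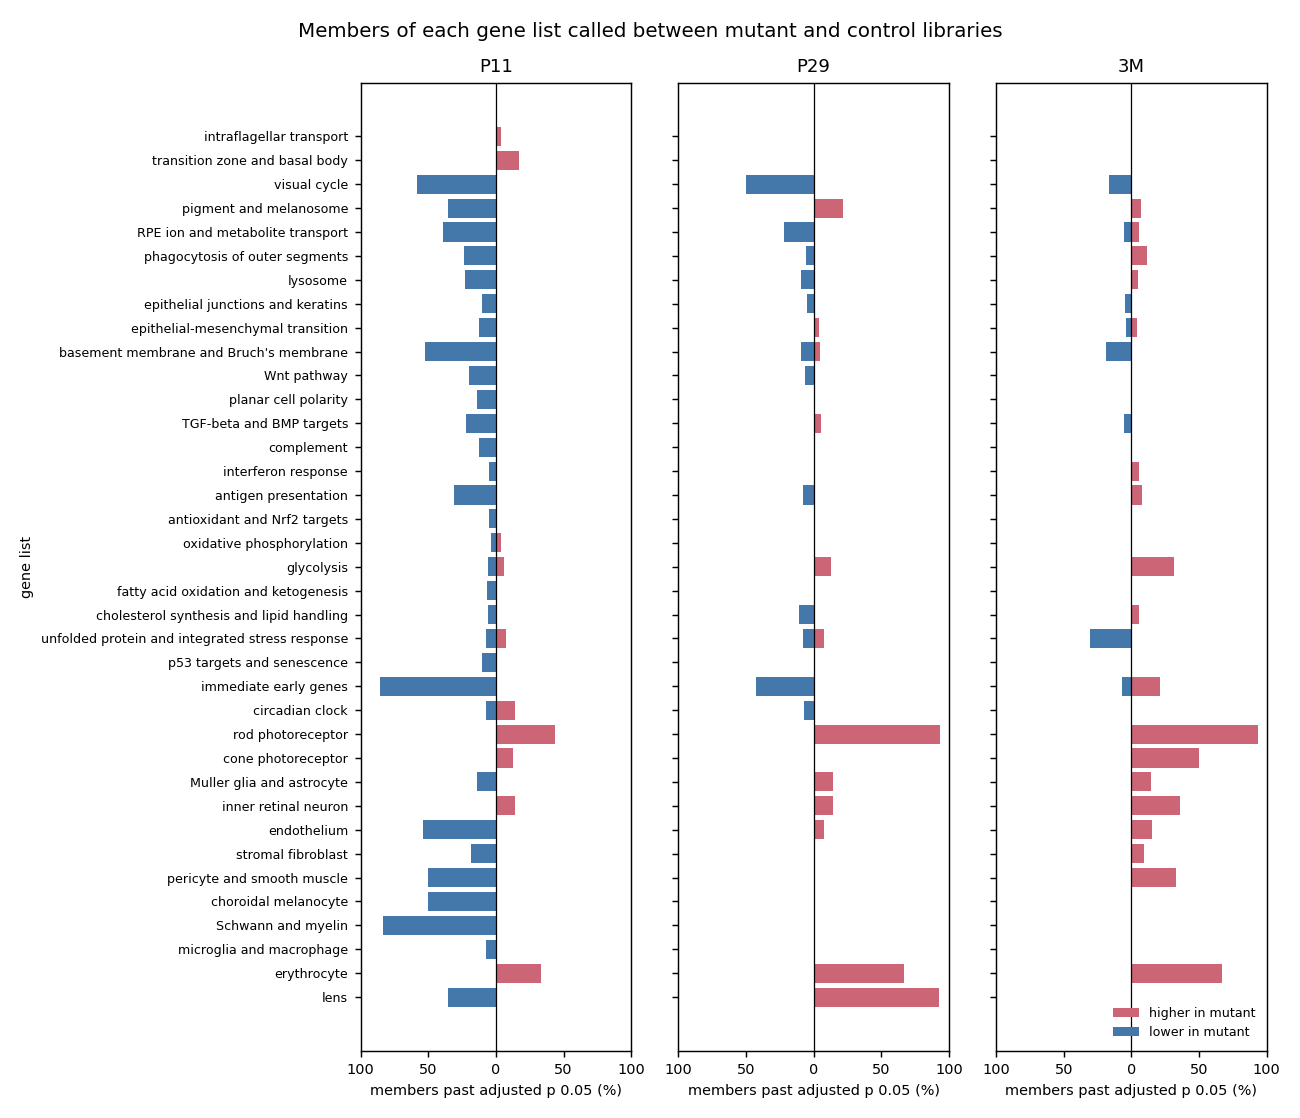
Share of the tested members of each gene list that passed the threshold between mutants and controls, in percent (x axis, higher in mutants to the right in red and lower to the left in blue), at P11, P29 and 3M; lists with no member called at any age are left out. Rod genes were higher in 7, 15 and 15 of 16 members at the 3 ages, and immediate early genes lower in 12, 6 and 1 of 14.

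At 3M the comparison asked about the adult tissue. Photoreceptor transcripts were higher in mutants and transcripts of the unfolded protein response were lower. Of 16 rod genes 15 rose (15 adjusted over the list alone), with Sag at 902 CPM ± 23.1 in mutants against 413 CPM ± 23.1 in controls (SD, n = 4). Cone genes rose in 4 of 8 (8), with the short-wave opsin Opn1sw at 1.69 (SE 0.24) and Pde6h at 1.59 (SE 0.32). Inner retinal neuron genes rose in 5 of 14 (5), with Tfap2b at 2.37 (SE 0.48) and Grm6 at least 6.44-fold higher over a group floor of 3 counts. Unfolded protein and stress response genes fell in 4 of 13 (1 higher and 5 lower over the list alone), with the chaperone Hspa5 at -0.35 (SE 0.07, edgeR adjusted p = 0.000239) and Manf at -0.87 (SE 0.17). In all, 262 genes were higher and 59 lower in mutants, against 231 and 158 in a fit to only these 8 libraries and 238 and 125 with voom.

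Basement membrane genes fell in 4 of 21 at 3M (6 over the list alone), with the collagen Col4a3 at -0.49 (SE 0.13) and Timp3 at -0.15 (SE 0.04). Visual cycle genes fell in 2 of 12 (2), among them Rpe65 at -0.15 (SE 0.04), and the list was lost with an estimated correlation (limma camera adjusted p = 0.0778). Glycolysis genes rose in 5 of 16 (5), with Pkm at 0.37 (SE 0.07) and Hk2 at 0.80 (SE 0.18). Immediate early genes rose in 3 of 14 and fell in 1 (3 and 2 over the list alone), with Klf4 at 0.97 (SE 0.13) and Fosb at 0.72 (SE 0.11), and the list as a set did not pass (limma camera adjusted p = 0.528). Pigment genes rose in 1 of 14 (1), Dct at 0.32 (SE 0.05). Transport genes rose in 1 of 18 and fell in 1, Slc16a1 at -0.28 (SE 0.06), with 2 and 1 over the list alone. Endothelial genes rose in 2 of 13 (3 higher and 1 lower over the list alone), Kdr at 1.88 (SE 0.34) and Esam at least 7.03-fold higher over a group floor of 3 counts. Of the 7 glial genes Gpr37 rose, with 20 counts in mutants and 1 in controls (ratio 20, 95% exact counting interval 3.19 to 828), and the list was lost with an estimated correlation (limma camera adjusted p = 0.0778).

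The 5 largest rises at 3M were Xist, Krt15, Snhg11, Abca8a and Ptprn, and the 5 largest falls Eif2s3y, Ddx3y, Uty, Kdm5d and F3. Xist was at 462 CPM ± 25 in mutants against 1.20 CPM ± 2.40 in controls (SD, n = 4), and Ddx3y at 52.8 CPM ± 6.74 against 181 CPM ± 9.87. Krt15, a keratin of basal epithelium, had no count in controls and 83 in mutants, at least 28-fold higher over the group floor of 3 counts. Snhg11 had 67 counts in mutants and 3 in controls (ratio 22.3, 95% exact counting interval 7.31 to 111). Abca8a rose by 3.16 (SE 0.67) and Ptprn by 2.67 (SE 0.72) on the log2 scale. Eif2s3y, Uty and Kdm5d, all on the Y chromosome like Ddx3y, had log2 fold changes of -2.55 (SE 0.39), -1.52 (SE 0.26) and -1.51 (SE 0.34), and F3, the coagulation tissue factor, -1.03 (SE 0.29).

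Of 41 lists 8 passed in camera at 3M, 5 upwards and 3 downwards, and 6 passed with an estimated correlation. These were rods (camera adjusted p = 1.51e-59, and 2.95e-11 with an estimated correlation), cones (2.1e-08 and 0.000509), inner retinal neurons (0.0122 and 0.0413), glycolysis (3.1e-05 and 0.00104), the unfolded protein response (5.55e-08 and 0.000145) and basement membrane (5.53e-06 and 0.00116). The visual cycle list (adjusted p = 0.0778) and the glial list (0.0778) were lost with the estimated correlation. With the rod score as a covariate 2 genes were higher and 1 lower, and with the sex score 5 were higher and 18 lower. The count of lower genes was 39 without control replicate 4 and 38 without mutant replicate 4.

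Several 3M calls no longer passed with 1 library left out. Timp3 passed without mutant replicate 3 and was lost without each of the other 7 libraries (adjusted p from 0.0536 without control replicate 2 to 0.104 without mutant replicate 4, log2 fold changes from -0.156 to -0.145). Rpe65 was lost without control replicate 1 (0.116), control replicate 2 (0.134), control replicate 4 (0.0507), mutant replicate 3 (0.0617) or mutant replicate 4 (0.297). Col4a3 was lost without control replicate 1 (0.171), control replicate 3 (0.0906), mutant replicate 1 (0.0558), mutant replicate 3 (0.139) or mutant replicate 4 (0.0589). F3 was lost without control replicate 3 (0.212), control replicate 4 (0.109), mutant replicate 3 (0.176) or mutant replicate 4 (0.118). Ptprn was lost without control replicate 2 (0.0932), control replicate 4 (0.113) or mutant replicate 3 (0.0620). Gpr37 was lost without control replicate 3 (0.0527) or control replicate 4 (0.0627). The glial list was lost without control replicate 1 (0.1), control replicate 3 (0.05), control replicate 4 (0.0789), mutant replicate 2 (0.0562) or mutant replicate 4 (0.1).

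The genotype effect was set between ages to ask which transcripts it moved alike and which it did not. At all 3 ages 27 genes were higher in mutants, among them Sag, Rom1, Krt5, Krt15 and Xist, and 10 were lower, among them Rpe65, Timp3 and Slc16a1, names that were picked after their values were seen. Shared calls numbered 33 higher and 63 lower between P11 and P29, against 6.55 and 5.47 for independent lists, 53 and 26 between P11 and 3M, against 8.54 and 2.17, and 84 and 19 between P29 and 3M, against 4.28 and 0.715. Over all 12303 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.057, 0.113 and 0.144 for these pairs of ages. Called in opposite directions were 24, 13 and 9 genes. No library was shared between the ages.

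The difference between mutants and controls varied with age for 495 genes in the joint edgeR test, with Cryba1 (adjusted p = 4.14e-26), Fosb (4.3e-21), Mbp (6.21e-15), Klf4 (6.21e-15) and Trf (2.11e-14) the 5 with the smallest p, followed by Crygs, Cryba2, Crygd, Mip and Cryaa. Cryba1 and the last 5 are lens genes, and Mbp is a myelin gene. Tissue carried into the libraries is not excluded for these, so the test does not place their change in the RPE. For Fosb, Klf4 and Trf the cell source was not tested either. Sex makeup was not separate from genotype at P29 and 3M. In controls Fosb was at 110, 528 and 129 CPM at P11, P29 and 3M, and Klf4 at 81.6, 288 and 74.5 CPM. Fosb fell by 1.61 (SE 0.13) at P11 and by 0.76 (SE 0.10) at P29 and rose by 0.72 (SE 0.11) at 3M on the log2 scale. Klf4, another immediate early transcription factor, changed by -1.0 (SE 0.15), -0.76 (SE 0.12) and 0.97 (SE 0.13) at the same ages. Mbp had log2 fold changes of -2.93 (SE 0.19), -0.44 (SE 0.18) and -0.15 (SE 0.19), and Trf, the iron carrier transferrin, -0.65 (SE 0.04), -0.16 (SE 0.04) and -0.03 (SE 0.04). Between pairs of ages the effect differed for 323 genes (P29 and P11), 105 (3M and P29) and 311 (3M and P11). With the rod score as a covariate the joint count was 168, and with the sex score 221.

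In controls, P29 was set against P11 to describe the change over this interval without the mutation. Visual cycle genes rose in 11 of 12 (11 adjusted over the list alone), with Rgr from 1340 CPM ± 86.3 to 5520 CPM ± 141 (SD, n = 4) and Rpe65 from 2410 CPM ± 12.7 to 7670 CPM ± 219. Transport genes rose in 13 of 18 and fell in 1 (13 and 1), with Kcnj13 at 1.86 (SE 0.08) and the lactate transporter Slc16a8 at 1.18 (SE 0.07). Interferon response genes rose in 13 of 19 and fell in 1 (13 and 1), with Ifi27 at 2.97 (SE 0.19) and Ifit3 at 2.26 (SE 0.23). Immediate early genes rose in 12 of 14 (12 higher and 1 lower over the list alone), with Egr1 at 2.35 (SE 0.08) and Jun at 2.02 (SE 0.10). Endothelial genes fell in all 13 (13), with Kdr at -2.45 (SE 0.21) and Flt1 at -2.16 (SE 0.24). Inner retinal neuron genes fell in all 14 (14), with Tfap2b at -2.59 (SE 0.25). Erythrocyte genes fell in all 6 (6), with Hbb-bs at -3.48 (SE 0.05) and Hbb-bt at -3.25 (SE 0.07). In all 2026 genes were higher and 1917 lower at P29, a balance that turned with median-of-ratios factors (1773 and 2167), DESeq2 (1845 and 2339), voom (1717 and 1825), a fit to only these 8 libraries (1577 and 1595) and the test against a 1.5-fold change (769 and 999).

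Rod genes fell in 12 of 16 and rose in 3 from P11 to P29 (12 and 3 over the list alone), with Gnat1 at 1.54 (SE 0.07) and Nr2e3 at -2.01 (SE 0.09). Basement membrane genes fell in 13 of 21 and rose in 3 (13 and 3), with Timp3 at 1.64 (SE 0.04) and Col8a2 at 1.30 (SE 0.07) among those that rose. Pigment genes fell in 6 of 14 and rose in 4 (7 and 4), with Pmel at -2.71 (SE 0.08) and Dct at -0.66 (SE 0.05). The 5 largest rises were Fam71a, Rgs1, Slco1b2, Iqcn and Ciart, of which the first 4 had no count at P11 and were at least 19.2, 17.6, 15.3 and 14.5-fold higher over a group floor of 3 counts, and Ciart, a repressor of the circadian clock, had 146 counts at P29 and 2 at P11 (ratio 59.1, 95% exact counting interval 16.1 to 493). The 5 largest falls were Grm6, Igdcc3, Tmem215, Avp and Mmp24. Avp had 325 counts at P11 and 1 at P29 (ratio 401, interval 71.5 to 15900), and Grm6, the receptor of ON bipolar cells, Igdcc3, Tmem215 and Mmp24 had no count at P29 and were at least 71.6, 69.2, 51.9 and 34.7-fold lower. In camera 29 of 41 lists passed, 15 upwards and 14 downwards, and 25 with an estimated correlation, where the lists lost were BBSome (adjusted p = 0.0697), Wnt pathway (0.0717), complement (0.0883) and stromal fibroblast (0.125). The Wnt list, which passed upwards, had a median of 0.28 and a mean of -0.20. With the rod score as a covariate 208 genes were higher and 112 lower.

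From P29 to 3M in controls the visual cycle rose further, in 10 of 12 genes (10 adjusted over the list alone), with Rgr from 5520 CPM ± 141 to 10100 CPM ± 286 and Ttr, the thyroxine and retinol transport protein, from 26200 CPM ± 329 to 35200 CPM ± 1110 (SD, n = 4). Unfolded protein response genes rose in 5 of 13 and fell in 1 (6 and 1), with Hspa5 at 0.47 (SE 0.07) and Manf at 0.96 (SE 0.17). Fatty acid oxidation genes rose in 4 of 15 (4), with Cpt1a at 0.48 (SE 0.12). Rod genes fell in all 16 (16), with Pde6g at -1.81 (SE 0.07) and Sag at -1.52 (SE 0.06). Immediate early genes fell in 9 of 14 (10), with Fosb at -2.03 (SE 0.11) and Klf4 at -1.95 (SE 0.13). Endothelial genes fell in 8 of 13 (9), with Kdr at -2.93 (SE 0.31) and Tie1 at least 18.3-fold lower over a group floor of 3 counts. Stromal fibroblast genes fell in 7 of 11 (9), with Dcn at -1.31 (SE 0.08) and Gsn at -1.66 (SE 0.21). Interferon response genes fell in 5 of 19 (6), with Ifit3 at -1.35 (SE 0.22) and Ifi44 at -3.42 (SE 0.73). Glycolysis genes fell in 5 of 16 (1 higher and 6 lower over the list alone), with Pkm at -0.62 (SE 0.07) and Aldoc at -0.88 (SE 0.15). Pigment genes fell in 6 of 14 with 1 higher (6 and 1), with Pmel at -1.84 (SE 0.09) and Dct at -0.82 (SE 0.05). In all 429 genes were higher and 1046 lower at 3M.

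The 5 largest rises from P29 to 3M were Erich5, Dgkb, Clca3a1, Myl4 and Thoc6, of which Erich5 had 48 counts at 3M and 2 at P29 (ratio 25.8, 95% exact counting interval 6.75 to 219) and the other 4 had log2 fold changes of 2.80 (SE 0.42), 2.62 (SE 0.90), 2.31 (SE 0.67) and 2.29 (SE 0.57). The 5 largest falls were Xist, Cryaa, Fcgr4, Ifi203 and Creb5, with Xist at 1.20 CPM ± 2.40 at 3M against 149 CPM ± 7.27 at P29 (SD, n = 4), Cryaa and Fcgr4 at least 19.6 and 16.9-fold lower over the group floor of 3 counts, Ifi203 with 63 counts at P29 and 1 at 3M (ratio 58.7, interval 10.2 to 2350), and Creb5 with 105 and 2 (ratio 48.9, interval 13.2 to 409). In camera 21 of 41 lists passed, 5 upwards and 16 downwards, and 17 with an estimated correlation, where the lists lost were epithelial-mesenchymal transition (adjusted p = 0.134), circadian clock (0.0562), inner retinal neuron (0.0562) and erythrocyte (0.0765). The transport list, which passed upwards, had a median of 0.19 and a mean of -0.05. With the rod score as a covariate 1 gene was higher and 0 lower, and with the sex score 17 were higher and 48 lower. Clca3a1 passed in edgeR without control P29 replicate 3 or control 3M replicate 1 and was lost without each of the other 6 libraries (adjusted p from 0.0736 without control P29 replicate 2 to 0.152 without control P29 replicate 1). Myl4 was lost without control P29 replicate 1 (0.0666), control P29 replicate 2 (0.0543) or control 3M replicate 4 (0.0650).

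The genotype effect was also set against the change with age in controls, across the 12303 genes, which are not independent replicates, using a change with age that shared no library with it. At P29 the genotype effect and the change from P11 to 3M had a Pearson r of -0.27 (jackknife SE over libraries 0.0681, Spearman coefficient -0.25), and at 3M the genotype effect and the change from P11 to P29 had r = -0.24 (SE 0.0620, Spearman coefficient -0.16). At P11 the genotype effect and the change from P29 to 3M had r = 0.01 (SE 0.0163, Spearman coefficient -0.02). Without the cell type list genes r was -0.26 at P29 and -0.22 at 3M, which removes only the listed genes. The rod list mean was higher in mutants at P29 (9.64 against 9.12 log2 CPM) and 3M (8.4 against 7.65). In controls it fell with age, from 9.6 at P11. The sex score was higher in P29 mutants, and lower in 3M than in P11 controls. Retina share and sex makeup may enter these values and cannot be told apart from genotype.

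The mean level of each of 15 cell type marker lists was compared between genotypes at each age with an exact two-sided permutation test over 70 assignments, whose smallest possible p is 0.0286. None of the 45 tests passed after Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.0677, with 19 at the unadjusted exact p of 0.0286 and 0 past adjustment with median-of-ratios scaling. With that smallest p, no list could pass over 45 tests unless many others reached it too, however large its difference. The lack of passes therefore does not speak against single lists. The technical measures below have the same smallest p. Among those 19 the lens list was higher by 4.50 on the log2 scale in P29 mutants and by 0.48 at 3M, the rod list by 0.19, 0.52 and 0.75 at P11, P29 and 3M, and the cone list by 1.40 at 3M. The 3M lens means were 0.31 log2 CPM in mutants and -0.16 in controls, near the floor of 3 counts, so that difference rests on few counts. Cryba1 was at 0.442 CPM in 3M mutants and 0 in controls, while Mip went the other way (0.946 and 2.04 CPM). The myelin list was lower by 3.42 in P11 mutants, the lens list was lower by 0.94 at P11, and the endothelial list was lower by 1.5 at P11 and higher by 0.78 at P29 and 0.81 at 3M. In each of these the 4 libraries of one genotype lay above all 4 of the other. Of the technical measures, 14660 genes had a count in P11 mutants against 13820 in controls, and 13990 against 13240 at 3M (exact permutation p = 0.0286 and adjusted p = 0.114 for each, n = 4). With the same p and adjusted p, reads assigned to no feature were 18.7% of all entries in 3M mutants against 19.3% in controls, reads aligned to several places 34.45% against 36.4% at P11, ambiguous reads 0.196% against 0.214% at P11, and the TMM factor 1.02 against 1.01 at P29. Mitochondrial transcripts took 5.842% of counts in P29 mutants against 5.052% in controls, and 5.805% against 4.825% at 3M (exact permutation p = 0.0571, adjusted p = 0.171 for each).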

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

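The tests of retina makeup, of dilution, of sex-linked genes, of shared RNA pools, of other splits of the libraries and of the lens list without background genes were chosen after the results were seen; the test of the second lens list was written before its values were seen.

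Rod transcripts were higher in mutants by 0.52 at P29 and 0.75 at 3M as list means on the log2 scale (SE 0.03 and 0.026). If the libraries held more retina of 1 fixed makeup, cone and rod lists would rise alike. At P29 the cone rise minus the rod rise was -0.15 (SE 0.13), which leaves this open. At 3M it was 0.65 (SE 0.23), which goes against a fixed makeup at that age but does not decide. That SE rests on 4 libraries per genotype, with an SD of the cone list of 0.45 in controls and 0.09 in mutants. Dilution of all RPE transcripts alike would move both RPE lists alike, while at P29 the pigment list minus the visual cycle list was 0.29 (SE 0.09). These lists were set against each other after they had been seen to differ, and choroidal melanocytes hold pigment transcripts too. The choroidal melanocyte list was higher by 0.33 in P29 mutants (exact permutation p = 0.2, adjusted p = 0.31). A differing share of melanocytes could therefore add to this difference, and dilution stays open. A different amount of adherent photoreceptor material, with cones and rods in fixed or changing shares, and a change in the RPE itself by genotype both stay open. With the rod score in the fit 3 genes were called at each of these ages, but 99.8% of the variance of that score lay between groups.

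Lens transcripts were higher in P29 mutants in 13 of 14 genes, among them 3 of the 4 that are not crystallins. Lens tissue carried into the libraries was predicted to raise the summed CPM of a second list of 11 lens genes in all 4 mutant libraries above all 4 controls. This was not met: the sums overlapped, at 23.7 CPM in mutants and 16.7 in controls (exact permutation p = 0.229), but 2 of the genes passed the expression filter and made up 95.2% of the control sum, so a low share of lens could not show. Chosen after that, the 9 other genes summed to 12.2 CPM ± 4.89 in mutants and 0.761 CPM ± 0.652 in controls with no overlap (exact permutation p = 0.0286, adjusted p = 0.129 over 9 tests, of which 0 passed). The smallest possible p of 0.0286 could not let 1 separated list pass over 9 tests. The sums go with carried lens tissue but do not establish it.

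Ddx3y was at 52.8 CPM in 3M mutants and 181 CPM in controls, and Xist at 462 CPM and 1.20 CPM. A single animal per library is argued against, since 21 of 24 libraries held both Xist and Ddx3y over 3 counts, with 1 of 4 among 3M controls. One RNA pool for the libraries of a group would leave 0 genes with at least 100 counts in 1 library and over 10 times less in another; there were 0 in each of the P11 and P29 groups, 2 in 3M controls (H19 and Lox) and 1 in 3M mutants (H19). H19, named like Lox after its values were seen, ran from 0.452 to 263 CPM among 3M controls and from 2.35 to 98.8 CPM among 3M mutants, and Avp from 12.2 to 63.2 CPM among P11 controls, values that go against a pool, but so few genes leave it open in each group. The coefficients of variation of Xist and Ddx3y within groups lay at a median percentile of 42 among genes of like level (11 values). For Xist the percentile was 3.5 in P11 mutants (3.08%) and 95.5 in P11 controls (25.5%). At the median these genes thus varied no more than others, which a shared pool would also give. Whether the sex makeup or the genotype lies behind the calls at 3M cannot be told apart, because 97.1% of the variance of the sex score lay between groups. The same holds at P29, where the score was 5.18 to 5.91 in mutants and 1.91 to 2.36 in controls. In 3M controls it was -6.96 to -3.27, so age and sex makeup cannot be told apart for 3M against P29 in controls. At P11 it was 2.65 to 2.88 in mutants and 1.29 to 2.01 in controls. A part of the sex makeup is therefore not excluded at P11.

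Of 395 groups of 4 libraries checked, 29 held a library standing apart from the other 3, against 19.8 for chance at 1 in 20; in 9 of them the other 3 were at 0, where any count stands apart, and the other 386 groups held 20 against 19.3. As list means on the log2 CPM scale these were inner retinal neurons in mutant P11 replicate 4 (4.98), pericytes in control P29 replicate 4 (3.78) and control 3M replicate 2 (2.82), myelin in mutant P11 replicate 3 (1.01) and erythrocytes in mutant P11 replicate 4 (10.5). In CPM, mutant P11 libraries stood apart for Ahi1 (183, replicate 3), Cep290 (328, replicate 3), Cspg4 (22.2, replicate 2), Mobp (0.491, replicate 1) and Vax2 (13.8, replicate 1). Control P11 replicate 3 did for Ciart (1.27). Mutant P29 libraries did for B2m (808, replicate 3), Crygf (15.8, replicate 3), Kcnj13 (478, replicate 4) and Nefl (25.4, replicate 1). Control P29 libraries did for Avp (0.357, replicate 1), Bfsp1 (0.369, replicate 3), Ddx3y (182, replicate 2), Krt5 (1.2, replicate 2), Sag (1070, replicate 2) and Xist (138, replicate 1). Control 3M libraries did for Clca3a1 (3.37, replicate 1), Gpr37 (0.421, replicate 1), Ifi203 (0.421, replicate 1), Ifit3 (41, replicate 3), Snhg11 (1.35, replicate 2) and Xist (4.79, replicate 3), and mutant 3M libraries for Ift20 (97.4, replicate 4) and Krt15 (17.1, replicate 3).

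The genotype effect differed between ages for 495 genes jointly, and for 323 between P29 and P11, 105 between 3M and P29 and 311 between 3M and P11. Excluding chance here concerns how these libraries were split, with shares of 1 in 35, the smallest that 35 splits can give, at 0.0343 after Benjamini-Hochberg adjustment over 12 results; if libraries of a group share a pool, chance between animals or pools is not excluded. Of 100 drawn splits 1, the real one, gave as many as 495, and the highest other gave 136. Of the 35 splits of 8 libraries, 1 gave as many called genes as the real split at P11 (853, highest other 68), P29 (350, 2) and 3M (321, 12), and for P29 against P11 (3943, 6) and 3M against P29 (1475, 13) in controls, so chance in the split can be excluded for these. It can be excluded for the lists at P11 (24, highest other 20, 1 of 35) and P29 (14, highest other 12, 1 of 35), and not for those at 3M, where 3 of 35 splits gave 8 or more (highest other 8). For the correlation of genotype effect with age, chance in the split can be excluded at P29 (r = -0.27, highest other 0.17, 1 of 35) and 3M (r = -0.24, highest other 0.195, 1 of 35), and not at P11 (r = 0.01, highest other 0.022, 12 of 35). These splits do not separate genotype from retina share or sex makeup.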

How the results depend on the processing

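The test against a 1.5-fold change and the calls on autosomal genes alone were chosen after the data were seen; the other settings were planned. Counts stayed within 1.5 times of the reported ones with median-of-ratios factors, DESeq2, both low-count filters and autosomal genes alone: P11 380 to 445 higher and 409 to 538 lower, P29 197 to 243 and 129 to 175, 3M at least 244 and 54 to 80. Replicate numbers did not pair libraries: 0 of 12 same-numbered pairs of an age correlated over 0.1 (-0.084 to 0.067), and 4 of 12 correlated best with their own number. With the number as a block the counts were 401 and 432 at P11, 196 and 148 at P29, 258 and 61 at 3M, 2039 and 1859, and 422 and 1017 in controls, with 473 interaction genes and 24, 14 and 9 lists.

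Voom with quality weights gave 298 lower genes at P11 and 125 at 3M, a fit to only the 8 libraries 158 lower at 3M, and fry 13 lists at 3M; the cause was not tested. The 1.5-fold test, stricter by construction, gave 4 higher and 31 lower at P11, 26 and 5 at P29, 50 and 3 at 3M, 769 and 999 for P29 against P11 and 22 and 445 for 3M against P29. Without cell type list genes the correlation with age at P11 was -0.007. Leaving out 1 library gave 38 (without mutant replicate 4) to 53 lower genes at 3M, with 39 without control replicate 4, and 297 to 485 higher at P11. The Ift20 log2 fold change at P29 was then -0.725 to -0.512, and its call ended without control replicate 1 (adjusted p = 0.0711) or 3 (0.075) or mutant replicate 2 (0.0962).

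The rod score as a covariate gave 24 higher and 63 lower genes at P11, 2 and 1 at P29, 2 and 1 at 3M, 208 and 112 for P29 against P11, 1 and 0 for 3M against P29, 168 interaction genes, 13, 5 and 1 lists, and an Ift20 log2 fold change at P29 of -1.13. The sex score gave 326 and 364 at P11, 2010 and 1838 for P29 against P11, 31 and 24 at P29, 5 and 18 at 3M, 17 and 48 for 3M against P29, 221 interaction genes and -0.70 for Ift20 at P29. Both scores lie almost wholly between groups (99.8% and 97.1% of their variance). Of 165 called values of named genes the rod score ended 116 and reversed 18, and the sex score 79 and 5. Reversed with the rod score were, as log2 fold changes at P29, Iigp1 (1.92), Crtap (1.26), Mlana (-0.36), Slc4a5 (0.029), Ctsd (0.12), Apoe (0.074) and Nefl (-0.14). At 3M these were Rpe65 (0.16), Dct (-0.12), Slc16a1 (0.16), Timp3 (0.034) and Hspa5 (0.013), with the unfolded protein list (median -0.034) and the glial list (median 0.93), whose set tests turned. For 3M against P29 they were Dgkb (-1.80), Thoc6 (-0.58), Dct (0.051), Cpt1a (-0.22), Hspa5 (-0.24) and Gsn (5.97). The sex score reversed Ptprn (-4.07), Rpe65 (0.01), Gpr37 (-0.85) and Kdr (-1.53) at 3M and Ifit3 (0.17) for 3M against P29.

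For single named genes and lists, over all settings, 4107 values kept their direction and side of the threshold, 368 no longer passed, 44 newly passed and 25 reversed. Other calls of named genes ended, by adjusted p, with median-of-ratios factors for Asprv1 (0.0506), and with DESeq2 for Lhx3 (0.365). They ended with voom for Chp2 (0.0678), Rpe65 at P11 (0.0709), H2-Eb1 (0.128), Crtap (0.0531), Hbb-bs (0.308), Hba-a2 (0.0931), Tfap2b at 3M (0.174), Gpr37 (0.126) and Grm6 at P29 (0.561) and 3M (0.0866). They ended without a low-count filter for Rpe65 (0.0675) and Timp3 (0.0524) at 3M and Clca3a1 (0.0535), and in the fit to 8 libraries for H2-Eb1 (0.0829) and Ogn (0.0553). The erythrocyte list at P11 was lost with median-of-ratios factors (0.0615) and the stricter filter (0.0511), and the microglia list with the latter (0.051). Depth limits the genes near the floor, where 1 count moves a fold.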

Other observations

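The tests of the epithelium and brain lists were written before their values were seen, and those on the lists without background genes were chosen afterwards.

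Gene groups whose change with age is not given above also moved in controls. From P11 to P29 skeletal muscle genes fell in all 6 (6 adjusted over the list alone; limma camera adjusted p = 0.00124, and 0.00608 with an estimated correlation). Lysosome genes rose in 12 of 22 and fell in 1 (12 and 2; 1.17e-06 and 0.000117), and circadian clock genes rose in 9 of 14 and fell in 1 (9 and 1; 0.000463 and 0.00434). From P29 to 3M microglia and macrophage genes fell in 7 of 14 and rose in 1 (9 and 2; 0.0282 and 0.0419), antigen presentation genes fell in 6 of 13 (9; 3.97e-05 and 0.00108) and lens genes in 9 of 14 (12; 0.00251 and 0.00881).

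Between genotypes at P11 the skeletal muscle list had a mean of 4.13 log2 CPM ± 0.21 in mutants and 3.58 ± 0.16 in controls (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0677), with 0 of its 6 genes past the threshold singly. The 2 tested mast cell genes had a mean of 0.15 log2 CPM ± 0.25 in P29 mutants and 1.45 ± 0.25 in controls (exact permutation p = 0.0286, adjusted p = 0.0677), against 1.89 and 2.14 at P11 (exact p = 0.686) and -0.96 and -1.21 at 3M (exact p = 0.429). The 3 tested ciliary body and iris genes had 0.91 ± 0.64 in 3M mutants and 0.06 ± 0.63 in controls (exact permutation p = 0.114, adjusted p = 0.19), against 3.25 and 3.41 at P11 (exact p = 0.714) and 1.33 and 0.72 at P29 (exact p = 0.457). Of the 9 lymphocyte genes 0 passed the expression filter.

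Keratins of stratified epithelium were among the largest rises in mutants, and surface epithelium of the eye carried into the libraries is a candidate explanation. It was predicted to raise the summed CPM of 17 other epithelial genes in all 4 mutant libraries above all 4 controls, which was not met at any age: 22.3 CPM in mutants and 19.7 in controls at P11, 44.2 and 34.4 at P29, and 24.1 and 17.2 at 3M (exact permutation p = 0.571, 0.171 and 0.0857). The 2 genes past the expression filter made up 65.6%, 86.8% and 87% of the control sums. Without them the sums were 10.2 CPM ± 3 and 6.77 CPM ± 2.95 at P11, 17.6 CPM ± 4.02 and 4.37 CPM ± 1.51 at P29, and 5.28 CPM ± 2.57 and 2.23 CPM ± 1.08 at 3M, without overlap at P29 alone (exact permutation p = 0.171, 0.0286 and 0.0857, adjusted p = 0.309, 0.129 and 0.257). The hypothesis stays open at each age.

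Avp was high in P11 controls and had no count in P11 mutants. Oxt, the oxytocin precursor, named after its values were seen, had 79 counts in P11 controls and 21 in mutants (edgeR adjusted p = 0.236), Gfap had a log2 fold change of -2.97 (SE 0.44), and the myelin list was lower by 3.42 in P11 mutants. Gfap was the only glial gene called, and the glial list had a median of 0.28, with 2 higher and 1 lower over the list alone. Brain tissue in the control libraries is a candidate source, since brain holds Avp, Oxt, Gfap and myelin transcripts, though nerve also holds those of myelin. Brain tissue was predicted to raise 11 other brain genes in all 4 controls, which was not met: they summed to 32.2 CPM in controls and 31.1 in mutants (exact permutation p = 0.857), with 78.7% of the control sum from 3 genes past the filter. The other 8 summed to 6.21 CPM ± 3.56 and 2.88 CPM ± 0.874 (exact permutation p = 0.143, adjusted p = 0.309), so the counts do not decide.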
